A study of Gallus gallus with 18 samples.

How the data were processed

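Whole-brain RNA of 9 HFP and 9 LFP chickens was measured on 18 one-colour arrays. Per the labels' protocols, 500 ng of total RNA per sample, from lipid-tissue columns, was spiked with control transcripts, copied into cRNA with Cy3 and hybridised. Per the submitters' processing notes and the file headers, the scans were read with Agilent Feature Extraction 10.5.1.1. The deposited spot values used here are linear intensity values, background-subtracted and spatially detrended within each array per the file headers, with no normalization between arrays. The flags for outlying, saturated and well-above-background spots come from the same files. The authors' deposited value table holds log2 values: each column follows the log2 processed signal of its own array, with a correlation of at least 0.997, all columns have a median of 7.99 and a 75th percentile of 10.6, and no value lies under the log2 of 5. It is therefore on a log2 scale with no centring of genes and with nearly the same median and 75th percentile for all arrays. The lowest values differed slightly between arrays, from 2.32 in LFP 18 to 2.38 in HFP 8. The method and software behind the value table are not given in the sources used here. One-colour values have no direction.

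Of 45220 spots on the array 43803 are not controls, and these carry 43603 probes. Spots with an outlier flag were removed, spots of 1 probe averaged on the log2 scale, and each array's 75th percentile of log2 processed signal subtracted. A probe was kept if well above background on at least 7 of the 9 arrays of at least 1 line, which left 36744. No spot was saturated. Slide 2 had 124 to 235 probes with an outlier flag per array, and the other slides at most 64. Gene symbols came from the names and accessions in the files, brought up to date with a reference table of assembly GRCg7b used for names only. A symbol was found for 26106 probes (11882 symbols), and the other probes kept the name in the files. The authors' values cover 40000 probes, of which 39950 matched a probe on the array. Probe coordinates are those of the files, on galGal3, and no annotation of that build was used.

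Lines were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (data.table version 1.17.8, statmod 1.5.0), 2-sided, with Benjamini-Hochberg adjustment over the 36744 probes and a threshold of 0.05. The fit had no covariate. Differences are HFP minus LFP. For a gene with several probes, the probe with the highest mean over all arrays stood for the gene. A probe not well above background on any array of a line has only a bound there: the bright line's mean was set against the dim line's mean of, per array, the higher of the probe's own signal and the lowest signal well above background, and the result is given as at least that fold. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, over lists with at least 5 genes. Within-line spread was tested by permuting the line labels 1000 times.

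The genes named in the text were fixed by a rule: among genes with a symbol past the threshold, the 12 with the largest positive and the 12 with the largest negative difference, up to 4 genes of smallest p in each list whatever their p, a few of which are not reported here, and TPH2, CRH, NR3C1, DRD4, HTR2C and DEAF1. Exceptions were RPS7, RPL15 and MAL, which complete the counts of their lists, and the probes in the closing observations, chosen after their values were seen. Groups, tests, lists, the naming rule and most alternatives were set before the data were examined. Those alternatives were normexp background correction (offset 50), quantile and median scaling, no filter or a filter on all 18 arrays, slide as a fixed or random block, scan day as a block, a trended and robust variance, array weights, the authors' value table, the mean of all probes of a gene, an estimated correlation and leaving out each array. Fits on scan day 1, on slide 2, on slide 3 and without slide 2, and against the LFP arrays of scan day 2 only, were added after the data were seen.

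On simulated data with the real means and spreads of the 36744 probes, limma's comparison of the lines recovered 71.6% of probes changed 1.5-fold, 92.5% of those changed 2-fold and 93.9% of those changed 4-fold, and called 11 unchanged probes. In the simulated list test camera called 0 of 31 lists without a change, and 2 lists when only the neuron list was raised. The simulated probes varied independently of each other and had no scan day effect. The list simulation therefore cannot tell how camera behaves on real lists, whose genes are correlated. Sex, kinship and housing of the birds are not in the labels. A probe of the W chromosome gene HINTW had scaled log2 signals of 4.65 ± 0.05 in HFP and 4.53 ± 0.06 in LFP (SD). It was well above background on all 9 arrays of each line, which argues against a difference in sex between the lines. Kinship and housing stay unknown here.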

Results

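Whole brains of adult chickens about 2 years old were compared between a line with high feather pecking (HFP) and a line with low feather pecking (LFP). Feather pecking is a behaviour of laying hens in which a bird pecks at or pulls out the feathers of others. RNA of 9 brains per line was hybridised, 1 sample to 1 array, to 18 one-colour Agilent chicken gene expression arrays of 60-base probes. The comparison of the 2 lines asks which transcripts differ in brain between birds of differing propensity to peck. Between 81.9% and 87.5% of the probes were well above background on an array, and the 75th percentile of the processed signal was between 1044 and 1680. The labels call the 9 samples of a line biological replicates and say nothing of kinship or housing, so p-values measure the spread between these samples only. Differences are HFP minus LFP on the log2 scale with their SE, for 9 arrays per line, and the number of arrays limits their precision.

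The largest differences concerned genes of several unrelated functions, with genes of the major histocompatibility complex (MHC) among both the rises and the falls. LGSN, which encodes lengsin, a lens protein of the glutamine synthetase family, was lower in HFP (-4.42 ± 0.426, adjusted p = 6.46e-06), where 1 of 9 arrays had it well above background. MTTP, which loads lipid onto apolipoprotein B, was higher (3.26 ± 0.455, adjusted p = 0.000243), with 1 of 9 LFP arrays well above background. GEMIN2, a part of the complex that assembles spliceosomal ribonucleoproteins, was 5.56-fold higher (2.47 ± 0.206, adjusted p = 1.48e-06). KCNJ15, an inwardly rectifying potassium channel, was 2.83-fold higher (1.50 ± 0.138, adjusted p = 3.86e-06). In limma, 4567 of 36744 probes differed between the lines, 2517 higher and 2050 lower in HFP (55.1% higher). With normexp background correction 2388 probes differed, 1720 higher and 668 lower (72.0% higher). Of 10922 genes with a symbol, each read through its brightest probe, 746 were higher and 517 lower. Most differences were small, with a median absolute log2 difference of 0.39 among the probes called, and 397 of these differed by 2-fold or more (169 higher, 228 lower). In 390 of the probes called the values of the lines did not overlap. Chance gives this for 0.00411% of probes not selected by their difference. That share is no reference for called probes and does not allow for scan day, given below. The first principal component, with 20.6% of the variance, separated the lines, and the second, with 12.5%, ran within both.

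**Figure D1:**
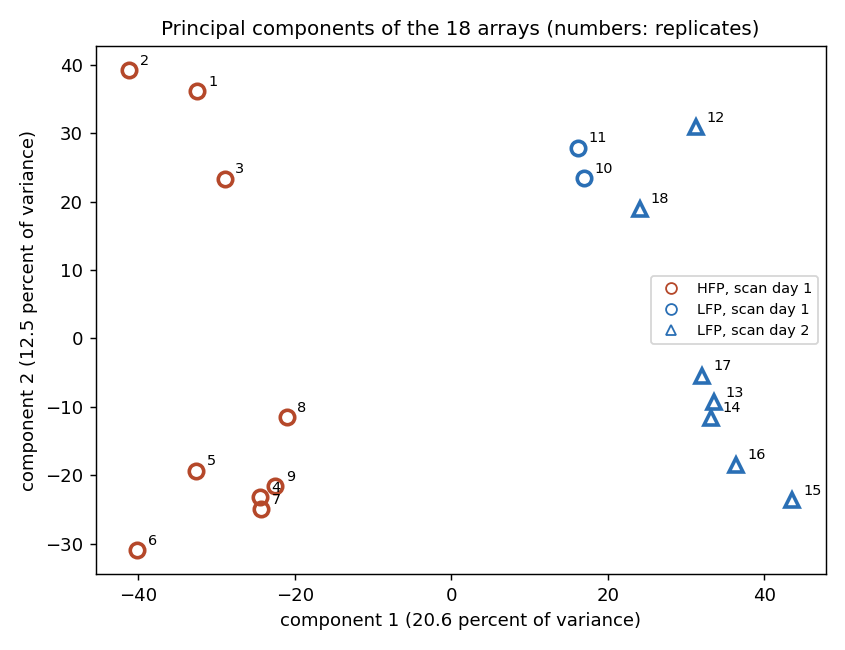
Principal components of the 18 arrays over 36305 probes, with component 1 (20.6% of the variance) on the x axis, component 2 (12.5%) on the y axis, colour for the line and circles or triangles for scan day 1 or 2. The HFP and LFP arrays lie on opposite sides of component 1, the LFP arrays of scan day 1 being the LFP arrays nearest to HFP.

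Scan day and slide were unevenly spread over the lines. All 9 HFP arrays and LFP replicates 10 and 11 were scanned on day 1, and the other 7 LFP arrays on day 2. Slide 2 held 3 HFP arrays and LFP 10, slide 3 held 3 HFP arrays and LFP 11, and slides 1, 4 and 5 held 1 line each. LFP 10 and LFP 11 both lay at position 4 of their slide. Differences within slide 2 or 3 therefore rest on 1 LFP array and cannot be told apart from position on the slide. With scan day as a block 569 probes differed (330 higher, 239 lower), 424 of them among the 4567, and 96.7% of the 4567 differences had the same sign. Within the 11 arrays of day 1 alone 732 probes differed. As day 2 held LFP only, the block's estimates are those of the day 1 arrays, so they rest on 2 LFP arrays. The arrays of day 1 and of slides 2 and 3 also helped to select the 4567 probes. Agreement in sign, here and below for named genes and lists, is thus partly built in and is no independent replication. With slide as a block 337 probes differed, 253 of them among the 4567. Within slide 2, 16 probes differed and 89.4% of the differences kept their sign, and within slide 3, 1 probe differed and 93.1% kept it. The blocked differences were smaller, at a median of 0.752 of the unblocked ones. Between the LFP arrays of the 2 days (2 against 7) 126 probes differed, and 5454 of 36744 had an unadjusted limma p under 0.05. The 2 arrays of day 1 limit the first of these counts. Between the HFP arrays of slides 1, 2 and 3 (3 each) 3 probes differed, and 1417 had an unadjusted limma p under 0.05.

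Among the 12 largest rises, MTTP had a signal of -6.03 ± 0.42 in HFP and -9.29 ± 1.39 in LFP (SD, n = 9, log2 relative to the array's 75th percentile). MTTP was well above background on 9 HFP arrays and on 1 LFP array, LFP 17, so its log2 differences, by block and slide too, rest on LFP signals near background and their size is uncertain. CHIR-B3, an immunoglobulin-like receptor of leukocytes, was higher by 2.93 ± 0.342 (adjusted p = 4.38e-05), and neither of its other 2 probes passed. GEMIN2 stood at -2.68 ± 0.25 in HFP and -5.15 ± 0.60 in LFP and KCNJ15 at -5.58 ± 0.35 in HFP and -7.08 ± 0.26 in LFP, both without overlap. The MHC class II beta chain BLB1 was higher by 2.09 ± 0.310 (adjusted p = 0.000407) and by 3.46 on another probe, while its other 3 probes lay between -1.43 and -0.55 and did not pass. BTN3A3L1, of the butyrophilin family, was higher by 2.69 ± 0.487, TMEM164 by 2.05 ± 0.366 and VPS26B, a retromer subunit, by 1.95 ± 0.260. MLLT6 was higher by 2.01, the axonemal dynein chain WDR63 by 1.60, the secreted factor ANGPTL6 by 1.55 and the sodium channel ACCN5 by 1.54, with adjusted p of 0.0101, 0.0220, 0.00988 and 0.00745. All 12 kept their sign with scan day as a block, where 5 passed: MTTP (3.56), CHIR-B3 (3.31), GEMIN2 (2.83), BLB1 (2.63) and KCNJ15 (1.38). The blocked differences of the rest were 3.16 for BTN3A3L1, 1.56 for TMEM164, 2.24 for MLLT6, 1.71 for VPS26B, 1.90 for WDR63, 1.27 for ANGPTL6 and 0.84 for ACCN5. Within slides 2 and 3, MTTP differed by 3.20 and 3.58, CHIR-B3 by 3.09 and 3.76, BTN3A3L1 by 2.12 and 4.07, GEMIN2 by 2.97 and 2.56 and BLB1 by 2.57 and 2.62. The same 2 values were 2.26 and 1.47 for TMEM164, 2.85 and 2.72 for MLLT6, 2.24 and 0.88 for VPS26B and 3.25 and 0.28 for WDR63. They were 0.31 and 2.05 for ANGPTL6, 0.99 and 1.37 for ACCN5 and 1.54 and 1.30 for KCNJ15.

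Among the 12 largest falls, LGSN had a signal of -8.83 ± 1.24 in HFP and -4.41 ± 0.57 in LFP (SD, n = 9) and was well above background on 1 HFP array, while its other probe, on none, was at least 2.24-fold lower. The size of LGSN's differences, by block and slide too, is therefore uncertain. BLEC2, a lectin-like receptor gene of the MHC, was not well above background on any HFP array and at least 5.06-fold lower (-3.16 ± 0.678, adjusted p = 0.00588). BG1, a butyrophilin-like gene of the MHC, was 7.46-fold lower (-2.90 ± 0.417, adjusted p = 0.000326), and 2 probes that overlap it were lower too, but its 2 probes elsewhere stood at -1.26 (adjusted p = 0.00832) and -0.35 (0.455). FAM101B, a filamin-binding protein, was at least 1.69-fold lower (-2.69 ± 0.193, adjusted p = 3.75e-07), MMRN1, a protein of platelets and endothelium, at least 2.41-fold (-2.35 ± 0.360) and SULT2B1, a hydroxysteroid sulfotransferase, at least 1.29-fold (-2.17 ± 0.320, but 0.0743 with normexp). None of these 3 was well above background on an HFP array, so their log2 differences here and by block and slide, like those of BLEC2, rest on HFP signals near background and only the bounds hold. The xenobiotic-sensing nuclear receptor NR1I3 differed by -2.56 ± 0.506 (adjusted p = 0.00357), but by only -0.44 with scan day as a block, -0.02 within slide 2 and -0.72 within slide 3, and its other probe stood at -0.02 (adjusted p = 0.935). VPS37B, of the ESCRT-I sorting complex, differed by -1.83 ± 0.434 (adjusted p = 0.0108), and by 0.08, 0.04 and 0.13 in those 3 settings. MPO, the myeloperoxidase of granulocytes, differed by -1.95 ± 0.438, CABCOCO1 by -1.91 ± 0.590, TC2N by -1.80 ± 0.337 and the secreted factor FAM3D by -1.78 ± 0.562. CABCOCO1 (adjusted p = 0.0415) and FAM3D (0.0458) lost their calls in 12 and 13 of the 18 fits that left out 1 array. With scan day as a block 11 of the 12 kept their sign and 5 passed: LGSN (-4.83), BG1 (-3.07), FAM101B (-2.72), SULT2B1 (-2.61) and TC2N (-2.33). Blocked differences were -3.46 for BLEC2, -1.83 for MMRN1, -1.64 for MPO, -2.74 for CABCOCO1 and -2.21 for FAM3D, none of which passed. Within slides 2 and 3, LGSN differed by -3.82 and -5.27, BLEC2 by -1.88 and -5.33, BG1 by -1.35 and -4.68, FAM101B by -3.20 and -2.36 and MMRN1 by -2.81 and -0.99. The same 2 values were -2.36 and -3.17 for SULT2B1, -1.37 and -1.74 for MPO, -1.35 and -3.87 for CABCOCO1, -2.32 and -2.05 for TC2N and -2.61 and -0.44 for FAM3D.

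**Figure D2:**
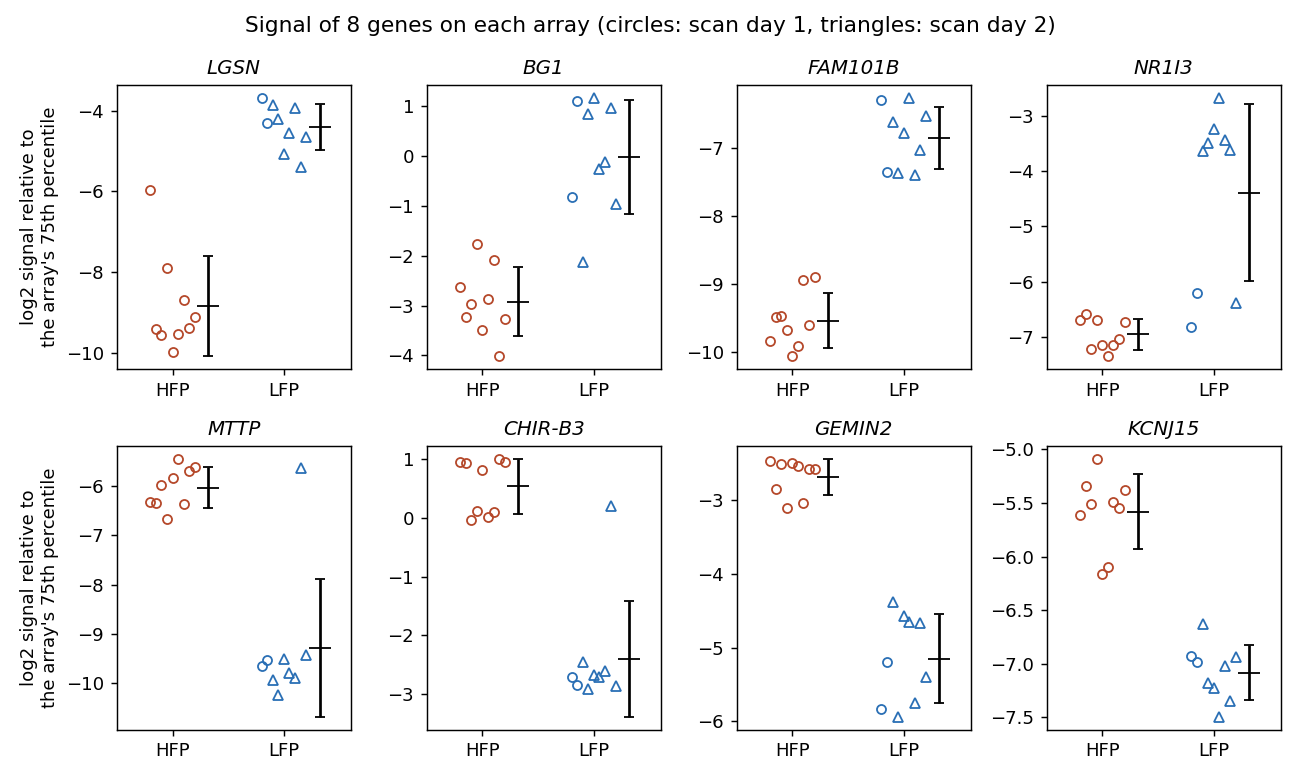
Log2 signal of LGSN, BG1, FAM101B, NR1I3, MTTP, CHIR-B3, GEMIN2 and KCNJ15 on each array relative to the array's 75th percentile (y axis) by line (x axis), with circles for scan day 1, triangles for scan day 2 and bars for the mean ± SD (n = 9). For NR1I3 the LFP arrays of scan day 1 lie beside the HFP arrays, and for MTTP and CHIR-B3 LFP 17 lies beside them.

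The probes lie, on build galGal3, at chromosome 3, 88529600 to 88529659 for LGSN, chromosome 4, 61648948 to 61650083 for MTTP, chromosome 5, 39998471 to 39998530 for GEMIN2 and chromosome 1, 110986841 to 110986900 for KCNJ15. BLEC2 (chromosome 16, 76939 to 76998) and BG1 (chromosome 16, 85439 to 85497) lie within the MHC of chromosome 16, FAM101B on chromosome 19, 6941270 to 6941332, NR1I3 on chromosome 25, 1775752 to 1775811 and VPS37B on chromosome 15, 5292037 to 5292096. Whether a probe lies in coding or untranslated sequence was not analysed here.

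Of 6 genes of serotonin, dopamine and stress signalling chosen in advance, the glucocorticoid receptor NR3C1 was higher in HFP by 0.46 ± 0.141 (adjusted p = 0.0381), and by 0.12 with scan day as a block, 0.36 within slide 2 and 0.14 within slide 3. That call was lost in 9 of the 18 fits that left out 1 array, with an adjusted p of up to 0.0701. The serotonin receptor HTR2C differed by 0.42 ± 0.160 (adjusted p = 0.0904) and the dopamine receptor DRD4 by 0.41 ± 0.295 (0.387), which did not pass. TPH2, the rate-limiting enzyme of serotonin synthesis in neurons, differed by 0.10 ± 0.248 (adjusted p = 0.824), the transcription factor DEAF1 by 0.02 ± 0.0493 (0.784) and the stress peptide CRH by 0.02 ± 0.166 (0.952).

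Genes were grouped in 32 lists of systems and cell types, of which 31 had at least 5 genes to test. Over the lists 715 genes were tested, of which 36 rose and 27 fell, or 8.81% against 11.6% of all genes. In the list accounts, a value "by scan day" has scan day as a block, and each list's median difference is followed by its medians by scan day and within slides 2 and 3. Of the 63 list genes called, 60 kept their sign with scan day as a block and 4 passed there (MYL2, ACACA, BG1 and BLB1), while AQP4 and ESAM were among those that changed sign. Within slide 2, 55 of the 62 with a value kept their sign, and within slide 3, 60 of 63.

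**Figure D3:**
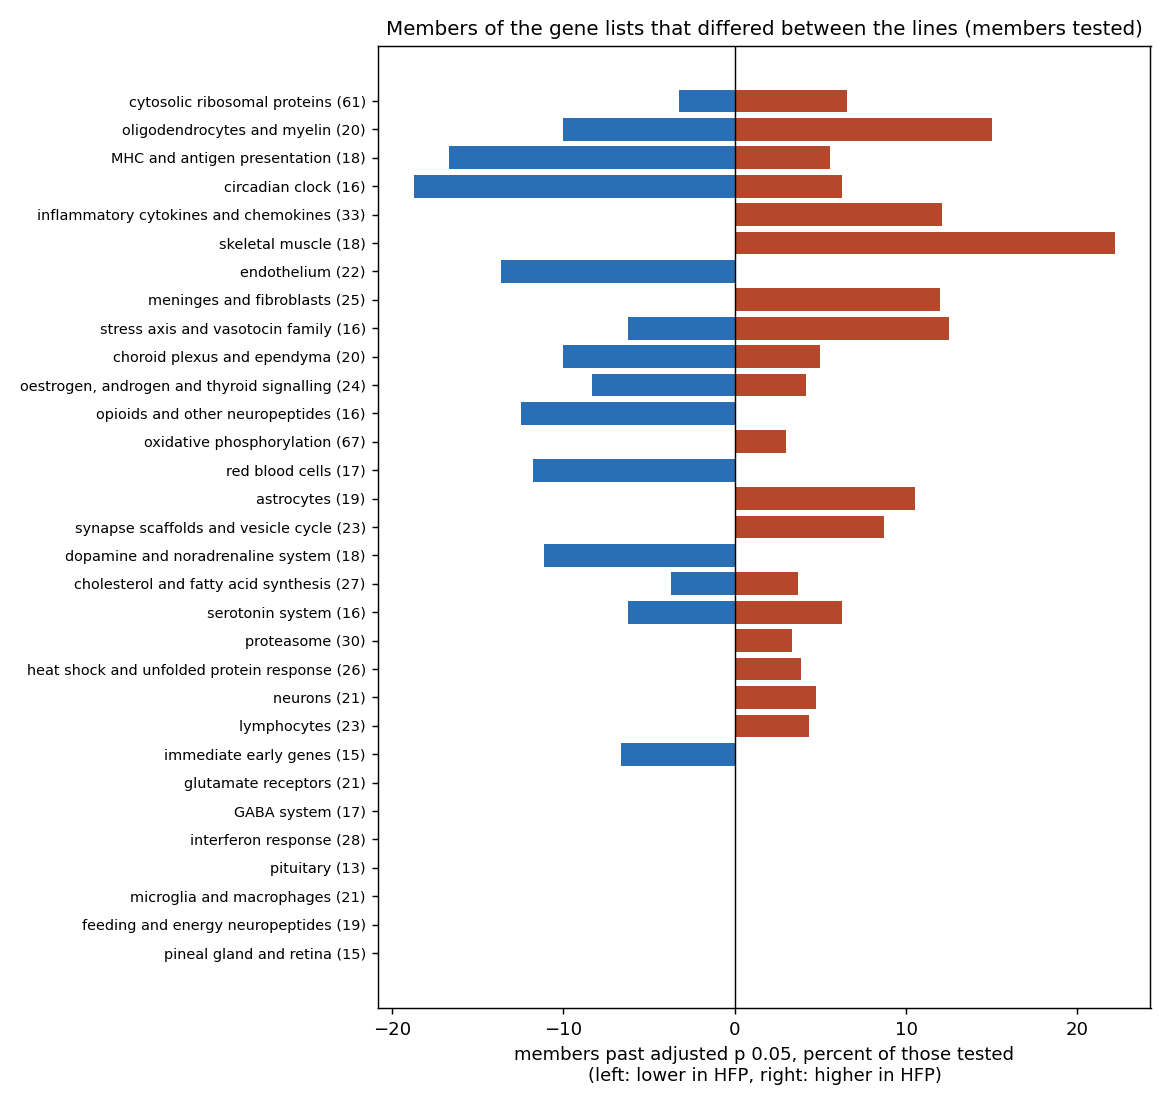
Share of the tested members of each gene list (y axis, members tested in brackets) that were higher (right) or lower (left) in HFP past an adjusted p of 0.05, in percent of the members tested (x axis). Of 715 list genes 36 were higher and 27 lower.

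In the serotonin system (16 genes tested), 1 rose, 1 fell and 14 did not pass (1 and 1 adjusted over the list alone). The receptor gene HTR1B (0.43 ± 0.113, adjusted p = 0.0180, 0.38 by scan day) rose and the receptor gene HTR1E (-0.50 ± 0.102, adjusted p = 0.00467, -0.36 by scan day) fell, though HTR1E stood at 0.0145 with normexp. The receptors HTR1D (-0.29 ± 0.105, adjusted p = 0.0758) and HTR2C (0.42 ± 0.160, adjusted p = 0.0904) did not pass. The list's median was 0.06, by scan day -0.06, in slide 2 -0.10 and in slide 3 -0.00. In the dopamine and noradrenaline system (18 genes), 0 rose, 2 fell and 16 did not pass (0 and 2 adjusted over the list alone). NR4A2 (-1.08 ± 0.255, adjusted p = 0.0101, -1.43 by scan day), a transcription factor of midbrain dopamine neurons, and the adrenoceptor gene ADRA1B (-0.51 ± 0.147, adjusted p = 0.0290, -0.81 by scan day) were the falls. The dopamine receptors DRD3 (-0.17 ± 0.0594, adjusted p = 0.0677) and DRD2 (0.20 ± 0.0905, adjusted p = 0.151) did not pass. Here the median was 0.03, by scan day -0.04, in slide 2 -0.19 and in slide 3 0.04. Of 21 glutamate receptors 0 passed in limma, over all genes and adjusted over the list alone, with 7 at an unadjusted p under 0.05. The smallest p belonged to GRM3 (-0.21 ± 0.0753, adjusted p = 0.0701) and GRIA1 (-0.22 ± 0.0842, adjusted p = 0.0888), followed by GRM2 (-0.17 ± 0.0668, adjusted p = 0.101) and GRID1 (0.25 ± 0.105, adjusted p = 0.125). Their median was -0.05, by scan day -0.04, in slide 2 0.02 and in slide 3 -0.02. Of 17 genes of the GABA system 0 passed in limma by either adjustment, with 1 at an unadjusted p under 0.05. Values were nearest to the threshold for GABBR2 (-0.27 ± 0.104, adjusted p = 0.0963), then for SLC32A1 (0.08 ± 0.0513, adjusted p = 0.299). The median was -0.05, by scan day -0.01, in slide 2 -0.00 and in slide 3 -0.01.

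Among 16 genes of the stress axis and vasotocin family, 2 rose, 1 fell and 13 did not pass (3 and 1 adjusted over the list alone). The glucocorticoid receptor NR3C1 (0.46 ± 0.141, adjusted p = 0.0381, 0.12 by scan day) and its co-chaperone FKBP5 (0.44 ± 0.130, adjusted p = 0.0326, 0.18 by scan day) rose. The mineralocorticoid receptor NR3C2 (-0.24 ± 0.0596, adjusted p = 0.0142, -0.20 by scan day) fell and HSD11B1B (0.29 ± 0.0951, adjusted p = 0.0556) did not pass. Their median was 0.11, by scan day -0.03, in slide 2 -0.16 and in slide 3 -0.10. None of 19 feeding and energy neuropeptides and receptors passed in limma by either adjustment, and 3 had an unadjusted p under 0.05. Closest were INS (-0.35 ± 0.127, adjusted p = 0.0798) and CCK (-0.27 ± 0.110, adjusted p = 0.120), then MC4R (0.43 ± 0.201, adjusted p = 0.166) and ADCYAP1 (0.16 ± 0.0827, adjusted p = 0.229). The feeding list had a median of -0.04, by scan day -0.26, in slide 2 -0.33 and in slide 3 -0.24. Of 16 opioid and other neuropeptide genes, 0 rose, 2 fell and 14 did not pass (0 and 2 adjusted over the list alone). The kappa opioid receptor OPRK1 (-0.45 ± 0.0915, adjusted p = 0.00413, -0.44 by scan day) and the substance P receptor TACR1 (-0.39 ± 0.102, adjusted p = 0.0184, -0.22 by scan day) fell. OPRL1 (-0.24 ± 0.122, adjusted p = 0.216) and NTS (-0.21 ± 0.109, adjusted p = 0.225) did not pass, and the list's median was -0.08, by scan day -0.09, in slide 2 -0.17 and in slide 3 -0.08. Of 15 immediate early genes, 0 rose, 1 fell and 14 did not pass (0 and 0 adjusted over the list alone). The nuclear receptor NR4A3 (-0.42 ± 0.130, adjusted p = 0.0426, -0.48 by scan day) fell, and EGR1 (-0.30 ± 0.156, adjusted p = 0.215) did not pass. Nor did DUSP1 (0.16 ± 0.0928, adjusted p = 0.289) or EGR4 (0.31 ± 0.192, adjusted p = 0.315), although EGR4 passed without HFP 2 (0.48, adjusted p = 0.0101). The median was -0.01, by scan day -0.07, in slide 2 0.12 and in slide 3 -0.16.

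In the list of oestrogen, androgen and thyroid signalling (24 genes), 1 rose, 2 fell and 21 did not pass (1 and 2 adjusted over the list alone). The steroid-synthesis enzymes HSD3B1 (-1.61 ± 0.300, adjusted p = 0.00235, -1.41 by scan day) and CYP11A1 (-0.65 ± 0.129, adjusted p = 0.00364, -0.81 by scan day) fell. Aromatase, CYP19A1 (0.71 ± 0.206, adjusted p = 0.0316, 0.73 by scan day), rose, and GHR (0.15 ± 0.0580, adjusted p = 0.0912) did not pass. The hormone list's median was 0.02, by scan day 0.03, in slide 2 -0.03 and in slide 3 -0.02. Of 16 circadian clock genes, 1 rose, 3 fell and 12 did not pass (1 and 4 adjusted over the list alone). ARNTL2 (-0.80 ± 0.116, adjusted p = 0.000355, -0.65 by scan day), a partner of CLOCK, and the repressor NFIL3 (-0.73 ± 0.213, adjusted p = 0.0320, -0.40 by scan day) fell. The repressor BHLHE40 (-0.53 ± 0.165, adjusted p = 0.0423, -0.06 by scan day) fell and the activator TEF (0.21 ± 0.0583, adjusted p = 0.0266, 0.08 by scan day) rose, while the median was -0.02, by scan day -0.01, in slide 2 0.13 and in slide 3 -0.01. Of 27 genes of cholesterol and fatty acid synthesis, 1 rose, 1 fell and 25 did not pass (1 and 0 adjusted over the list alone). ACACA (0.50 ± 0.0560, adjusted p = 3.04e-05, 0.40 by scan day), which makes malonyl-CoA for fatty acids, rose. THRSP (1.06 ± 0.372, adjusted p = 0.0694) and ELOVL6 (-0.20 ± 0.113, adjusted p = 0.268) did not pass, and the median was -0.00, by scan day 0.07, in slide 2 0.04 and in slide 3 0.06. Of 26 genes of the heat shock and unfolded protein response, 1 rose, 0 fell and 25 did not pass (0 and 0 adjusted over the list alone). The endoplasmic reticulum chaperone HYOU1 (0.26 ± 0.0776, adjusted p = 0.0377, 0.28 by scan day) rose and HSPD1 (0.13 ± 0.0488, adjusted p = 0.0923) did not pass. Neither did CANX (-0.32 ± 0.124, adjusted p = 0.102) or HSPB8 (0.18 ± 0.0739, adjusted p = 0.108), and the median was 0.08, by scan day 0.05, in slide 2 -0.03 and in slide 3 0.06.

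Of 18 genes of the MHC and antigen presentation, 1 rose, 3 fell and 14 did not pass (2 and 4 adjusted over the list alone). BLB1 rose (2.09) and BG1 fell (-2.90). The class I-like gene YFV (-0.82 ± 0.207, adjusted p = 0.0147, -0.63 by scan day) and TAPBP (-0.67 ± 0.210, adjusted p = 0.0431, -0.76 by scan day), which helps load peptide onto class I molecules, fell too. The MHC list's median was -0.11, by scan day 0.00, in slide 2 0.08 and in slide 3 0.01. Of 28 interferon response genes 0 passed in limma by either adjustment, with 4 at an unadjusted p under 0.05. Values were CMPK2 (-0.38 ± 0.145, adjusted p = 0.0951) and IFI27L2 (-0.18 ± 0.0802, adjusted p = 0.143), then ADAR (0.15 ± 0.0693, adjusted p = 0.162) and MYD88 (0.15 ± 0.0710, adjusted p = 0.176). The interferon list had a median of -0.06, by scan day 0.07, in slide 2 0.20 and in slide 3 -0.05. None of 21 microglia and macrophage genes passed in limma by either adjustment, and 5 had an unadjusted p under 0.05. Among them were CYBB (-0.21 ± 0.0730, adjusted p = 0.0619), LY86 (0.25 ± 0.106, adjusted p = 0.122) and TREM2 (0.36 ± 0.153, adjusted p = 0.128). The microglia median was 0.06, by scan day 0.22, in slide 2 0.29 and in slide 3 0.13. Of 23 lymphocyte genes, 1 rose, 0 fell and 22 did not pass (1 and 0 adjusted over the list alone). CD28 (0.94 ± 0.176, adjusted p = 0.00239, 0.98 by scan day), a costimulatory receptor of T cells, rose, and CCL4 (0.39 ± 0.189, adjusted p = 0.179) did not pass. The same held for PTPRC (-0.28 ± 0.136, adjusted p = 0.191) and JCHAIN (1.74 ± 0.876, adjusted p = 0.204), and the lymphocyte median was 0.05, by scan day 0.46, in slide 2 0.58 and in slide 3 0.39.

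Of 33 inflammatory cytokine and chemokine genes, 4 rose, 0 fell and 29 did not pass (4 and 0 adjusted over the list alone). The rises were TNFSF15 (0.54 ± 0.106, adjusted p = 0.00349, 0.56 by scan day), IL1R2 (0.83 ± 0.173, adjusted p = 0.00518, 0.96 by scan day), a decoy receptor for interleukin-1, and its signalling receptor IL1R1 (0.39 ± 0.0966, adjusted p = 0.0131, 0.38 by scan day). The complement gene C4 (0.39 ± 0.0881, adjusted p = 0.00846, 0.49 by scan day) was the last of them, and the median was 0.01, by scan day 0.19, in slide 2 0.25 and in slide 3 0.15. Of 17 red blood cell genes, 0 rose, 2 fell and 15 did not pass (0 and 2 adjusted over the list alone). The globins HBBR (-0.65 ± 0.153, adjusted p = 0.0106, -0.38 by scan day) and HBB (-0.59 ± 0.175, adjusted p = 0.0348, -0.58 by scan day) fell, though HBB stood at 0.0883 with normexp. HBAD (-0.37 ± 0.155, adjusted p = 0.129) and CA2 (0.14 ± 0.0635, adjusted p = 0.168) did not pass, and the red cell median was -0.15, by scan day -0.33, in slide 2 -0.38 and in slide 3 -0.25. Of 22 endothelium genes, 0 rose, 3 fell and 19 did not pass (1 and 5 adjusted over the list alone). The efflux pump ABCB1 (-0.46 ± 0.0970, adjusted p = 0.00549, -0.39 by scan day) and the glucose transporter SLC2A1 (-0.28 ± 0.0644, adjusted p = 0.00991, -0.20 by scan day) of the blood-brain barrier fell. The adhesion gene ESAM (-0.28 ± 0.0893, adjusted p = 0.0442, 0.01 by scan day) fell as well, but stood at 0.0960 with normexp, and SLC16A1 (0.14 ± 0.0486, adjusted p = 0.0644) did not pass. The endothelial median was -0.08, by scan day -0.02, in slide 2 -0.04 and in slide 3 -0.04. Of 25 genes of meninges and fibroblasts, 3 rose, 0 fell and 22 did not pass (6 and 1 adjusted over the list alone). The collagens COL1A2 (0.32 ± 0.0937, adjusted p = 0.0331, 0.40 by scan day) and COL3A1 (0.27 ± 0.0841, adjusted p = 0.0411, 0.43 by scan day) rose. The proteoglycan LUM (0.36 ± 0.109, adjusted p = 0.0395, 0.37 by scan day) rose and COL12A1 (-0.21 ± 0.0679, adjusted p = 0.0508) did not pass, and the median was 0.06, by scan day 0.15, in slide 2 0.14 and in slide 3 0.08.

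Of 21 neuron genes, 1 rose, 0 fell and 20 did not pass (0 and 0 adjusted over the list alone). The surface glycoprotein THY1 (0.20 ± 0.0579, adjusted p = 0.0364, 0.13 by scan day) rose, and STMN2 (0.15 ± 0.0519, adjusted p = 0.0657) did not pass. Nor did SYN2 (0.15 ± 0.0585, adjusted p = 0.0966) or SNAP25 (-0.25 ± 0.105, adjusted p = 0.136), and the neuron median was 0.04, by scan day 0.03, in slide 2 0.02 and in slide 3 0.04. Of 20 genes of oligodendrocytes and myelin, 3 rose, 2 fell and 15 did not pass (4 and 2 adjusted over the list alone). The transcription factors MYT1 (0.74 ± 0.217, adjusted p = 0.0334, 0.94 by scan day) and OLIG2 (0.33 ± 0.100, adjusted p = 0.0381, 0.13 by scan day) rose. ENPP6 (0.32 ± 0.0983, adjusted p = 0.0382, 0.44 by scan day) rose, and ASPA (-0.39 ± 0.104, adjusted p = 0.0201, -0.49 by scan day), which cleaves N-acetylaspartate, fell. The myelin gene MAL (-0.27 ± 0.0818, adjusted p = 0.0387, -0.10 by scan day) fell, and the median was 0.20, by scan day -0.08, in slide 2 -0.15 and in slide 3 -0.07. Of 19 astrocyte genes, 2 rose, 0 fell and 17 did not pass (2 and 0 adjusted over the list alone). The bicarbonate transporter SLC4A4 (0.35 ± 0.0776, adjusted p = 0.00702, 0.17 by scan day) and the water channel AQP4 (0.25 ± 0.0750, adjusted p = 0.0388, -0.02 by scan day) rose. FGFR3 (-0.26 ± 0.0899, adjusted p = 0.0635) and GLUL (-0.30 ± 0.108, adjusted p = 0.0822) did not pass, and the astrocyte median was 0.05, by scan day -0.01, in slide 2 0.08 and in slide 3 -0.05. Of 20 genes of choroid plexus and ependyma, 1 rose, 2 fell and 17 did not pass (1 and 2 adjusted over the list alone). The water channel AQP1 (0.85 ± 0.181, adjusted p = 0.00546, 0.98 by scan day) rose, and RSPH4A (-0.87 ± 0.198, adjusted p = 0.00850, -0.85 by scan day), a part of motile cilia, fell. KL (-0.60 ± 0.173, adjusted p = 0.0292, -0.30 by scan day) fell, PTGDS (0.24 ± 0.0978, adjusted p = 0.115) did not pass, and the median was 0.16, by scan day 0.09, in slide 2 0.06 and in slide 3 -0.07.

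Of 13 pituitary genes 0 passed in limma by either adjustment and 0 had an unadjusted p under 0.05. Values were CGA (-0.40 ± 0.335, adjusted p = 0.462) and PITX1 (0.20 ± 0.181, adjusted p = 0.513), then GHRHR (-0.12 ± 0.141, adjusted p = 0.603). The pituitary median was -0.09, by scan day -0.01, in slide 2 -0.38 and in slide 3 0.09. Of 15 genes of pineal gland and retina 0 passed in limma by either adjustment, with 1 at an unadjusted p under 0.05. The leading values were GRK1 (-0.25 ± 0.116, adjusted p = 0.174) and RAX2 (0.16 ± 0.0872, adjusted p = 0.240), then OPN1LW (-0.25 ± 0.147, adjusted p = 0.281) and PDE6G (0.11 ± 0.0621, adjusted p = 0.284). For pineal gland and retina the median was 0.07, by scan day 0.18, in slide 2 0.01 and in slide 3 0.31. Of 18 skeletal muscle genes, 4 rose, 0 fell and 14 did not pass (4 and 0 adjusted over the list alone). All 4 encode contractile proteins, TNNC2 (0.76 ± 0.153, adjusted p = 0.00402, 0.49 by scan day) and TNNI1 (0.39 ± 0.0979, adjusted p = 0.0145, 0.25 by scan day) among them. The others were MYL2 (0.39 ± 0.109, adjusted p = 0.0274, 0.76 by scan day) and TNNT3 (0.51 ± 0.153, adjusted p = 0.0369, 0.84 by scan day), and the muscle median was -0.02, by scan day -0.02, in slide 2 -0.06 and in slide 3 -0.03. Of 23 genes of synapse scaffolds and the vesicle cycle, 2 rose, 0 fell and 21 did not pass (2 and 0 adjusted over the list alone). The active zone gene RIMS1 (0.27 ± 0.0690, adjusted p = 0.0166, 0.04 by scan day) and the fusion protein STX1A (0.25 ± 0.0712, adjusted p = 0.0294, 0.14 by scan day) rose. ERC2 (0.15 ± 0.0737, adjusted p = 0.190) and PCLO (0.25 ± 0.147, adjusted p = 0.286) did not pass, and the synapse median was 0.05, by scan day 0.04, in slide 2 0.06 and in slide 3 0.03.

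Of 61 cytosolic ribosomal protein genes, 4 rose, 2 fell and 55 did not pass (4 and 2 adjusted over the list alone). RPL35A (0.26 ± 0.0522, adjusted p = 0.00356, 0.10 by scan day) and RPS10 (0.26 ± 0.0659, adjusted p = 0.0151, 0.14 by scan day) rose, and so did RPS7 (0.19 ± 0.0552, adjusted p = 0.0313, 0.18 by scan day) and RPL15 (0.18 ± 0.0511, adjusted p = 0.0326, 0.12 by scan day). RPL3L (-1.39 ± 0.366, adjusted p = 0.0189, -1.23 by scan day), a paralogue of RPL3 known from muscle, and RPS24 (-0.27 ± 0.0725, adjusted p = 0.0228, -0.37 by scan day) fell. With 50 of 61 differences above 0, the ribosomal median was 0.06, by scan day 0.03, in slide 2 0.04 and in slide 3 0.02. Of 67 oxidative phosphorylation genes, 2 rose, 0 fell and 65 did not pass (1 and 0 adjusted over the list alone). The complex I genes NDUFA2 (0.35 ± 0.0476, adjusted p = 0.000218, 0.32 by scan day) and NDUFA6 (0.19 ± 0.0594, adjusted p = 0.0436, 0.07 by scan day) rose. UQCRB (-0.27 ± 0.0970, adjusted p = 0.0783) and NDUFB4 (0.15 ± 0.0568, adjusted p = 0.0823) did not pass, and the median was 0.04, by scan day -0.05, in slide 2 -0.08 and in slide 3 -0.04. Of 30 proteasome genes, 1 rose, 0 fell and 29 did not pass (0 and 0 adjusted over the list alone). PSMD7 (0.11 ± 0.0353, adjusted p = 0.0485, 0.02 by scan day) rose, a call lost in 17 of the 18 fits that left out 1 array, and PSMC6 (0.16 ± 0.0548, adjusted p = 0.0583) did not pass. Nor did PSMA3 (0.12 ± 0.0452, adjusted p = 0.0920) or PSMB7 (0.11 ± 0.0433, adjusted p = 0.0945), and the proteasome median was 0.07, by scan day 0.03, in slide 2 -0.02 and in slide 3 0.03. The W chromosome list had 2 genes on the arrays, too few for a list test, and neither ATP5A1W (-0.04 ± 0.0519, adjusted p = 0.636) nor HINTW (0.00 ± 0.0580, adjusted p = 0.986) passed, although another probe of HINTW was higher by 0.12 (adjusted p = 0.0356).

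As a set, only the cytosolic ribosomal proteins passed limma's camera test against all other genes (up, adjusted p = 0.0231 with a preset correlation of 0.01), with 8 of the 31 lists at an unadjusted p under 0.05. The call was lost with an estimated correlation (adjusted p = 0.953), which left 0 lists, also at an unadjusted p under 0.05. With scan day as a block its adjusted p was 0.569, and with slide as a block 0.734. The scan day block instead called 6 other lists: inflammatory genes (up, adjusted p = 0.00635), lymphocytes (up, 0.00635), microglia (up, 0.0436), red blood cells (down, 0.00635), feeding neuropeptides (down, 0.0235) and oxidative phosphorylation (down, 0.0458), a contrast that rests on 2 LFP arrays. These calls too use the preset correlation, whereas the estimate without a block was 0.524 for lymphocytes, 0.350 for microglia, 0.332 for red blood cells and 0.180 for inflammatory genes. It was 0.299 for oxidative phosphorylation and 0.0963 for feeding neuropeptides. As a mean over members relative to all arrays, HFP 4 was the highest array for lymphocytes (1.34), microglia (0.73) and inflammatory genes (0.51). LFP 11, 1 of those 2 LFP arrays, was the lowest array for microglia (-0.38) and inflammatory genes (-0.27). For lymphocytes it was the lowest array of scan day 1 (-0.77). The block was not refitted without HFP 4 or without LFP 11. By fry, whose directional test asks whether the genes of a list move, on balance, one way, 0 lists passed and 5 had an unadjusted p under 0.05. Its mixed test, which asks whether genes change in either direction, passed for 20 lists. Neither fry test compares a list with other genes. The median and mean differed in sign for the feeding list (-0.04 and 0.05), for skeletal muscle (-0.02 and 0.03) and for cholesterol and fatty acid synthesis (-0.00 and 0.03).

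The spread of expression within a line was compared over 10922 genes as the variance in HFP over that in LFP. The median log2 ratio was -0.10 (2-sided permutation p = 0.650, 1000 permutations), with a median SD of 0.166 in HFP and 0.173 in LFP. In 46.5% of the genes the variance was the greater in HFP. With the 9 HFP arrays against the 7 LFP arrays of scan day 2 the ratio was -0.05, and without slide 2 it was -0.23. The ratio turned positive with normexp and with quantile scaling, as given below. Pairs of arrays of a line differed by an SD of 0.287 to 0.512 over the probes well above background on all arrays, and pairs between the lines by 0.398 to 0.579. Replicate spots on 1 array differed by 0.0656 to 0.0921. The spot value is a median over 50 probes, so its size cannot be set against that of the pairs.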

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

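No test in this part was chosen after its result was seen, since each value was singled out by the same measure: the gap of the highest or lowest array of a line to its nearest neighbour, as a share of the line's range. Chance alone picks about 1 in 20 groups, so 14.8 of the 297 groups of genes and 3.1 of the 62 groups of list scores would be expected, and 17 and 12 were found. The groups share the same arrays and are not independent: HFP 4, LFP 15 and LFP 18 were each picked for several lists. The 12 against 3.1 is therefore no test of an excess. A list score is the mean over members of the log2 value relative to the mean of all arrays, and other values are log2 signals relative to the array's 75th percentile. Each value below lay far from the other 8 arrays of its line, whose median follows it.

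HFP 4 stood apart in immune genes. Its score was 0.88 against -0.21 for MHC genes, 0.56 against -0.08 for interferon genes, 0.73 against -0.07 for microglia and 0.51 against -0.04 for inflammatory genes. Its lymphocyte score of 1.34 was the highest of all arrays but was not singled out by the gap measure. Among the members of the 4 lists singled out, the excess over the mean of the other HFP arrays reached 2.88 for the class I gene BF2, 2.61 for SAMD9L, 2.33 for CX3CR1 and 3.29 for CCL26. The median excess of members was 1.15 for MHC genes, 0.60 for interferon genes, 0.87 for microglia and 0.46 for inflammatory genes. For lymphocytes it was 1.58. Single genes of HFP 4 were BLB1 (1.28 against -0.13), CYBB (-4.44 against -4.72), PTPRC (-4.67 against -5.46) and THRSP (-5.43 against -3.48).

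LFP 17 carried HFP-like signals of MTTP (-5.63 against -9.73) and CHIR-B3 (0.21 against -2.71), the genes with the largest rises in HFP. ACCN5 was low in LFP 12 (-6.70 against -4.56) and WDR63 high in HFP 6 (-4.05 against -4.98). HFP 2 was apart in EGR1 (2.26 against 3.23), EGR4 (-2.19 against -0.67) and IL1R1 (-3.40 against -2.86). Further single genes were ERC2 in HFP 6 (-1.64 against -1.18), GHRHR in LFP 13 (-4.54 against -3.97), PDE6G in LFP 13 (-0.60 against -0.43), GRID1 in LFP 18 (-0.14 against -0.77), PSMD7 in LFP 10 (4.36 against 4.19) and UQCRB in LFP 10 (0.18 against 0.65). LFP 15 was apart in the scores of feeding neuropeptides (-0.82 against 0.03), oligodendrocytes (-0.56 against -0.02) and synapse genes (0.14 against -0.04), and LFP 18 in those of ribosomal proteins (-0.17 against -0.00) and glutamate receptors (0.25 against -0.01). Other scores were GABA genes in LFP 12 (0.0792 against 0.02), astrocytes in HFP 5 (-0.13 against 0.06) and oxidative phosphorylation in HFP 6 (0.15 against -0.00). Among array measures, LFP 10 had 124 probes with an outlier flag against a median of 5.5, and it shared slide 2 with the 3 HFP arrays that also had over 100.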

How the results depend on the processing

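The fits on scan day 1, slide 2 and slide 3 and without slide 2 were chosen after the data were seen. The count of 4567 probes stayed within 1.5 times under quantile scaling (4644), median scaling (4465), no filter (4141), the filter on all 18 arrays (4379), a random slide block (6015), a trended variance (4620), array weights (5204), the value table (4843) and without slide 2 (3352). It was 2388 with normexp, 337 with slide as a block, 569 with scan day as a block, 732 on scan day 1, 16 on slide 2 and 1 on slide 3. The cause was not tested. The random slide block estimated a correlation of -0.0513 within slides, and its 6015 probes included all 4567. Its count is therefore no check against a slide effect. Leaving out 1 array gave 3685 to 5052 probes, the highest counts being those without LFP 10 (5052) and LFP 11 (4900), the LFP arrays of scan day 1. HFP against the LFP arrays of scan day 2, a fit also chosen after the data were seen, gave 5918, of which 4055 were among the 4567. No paired analysis was possible because the lines share no replicate numbers.

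The 1 list called became 0 with normexp, array weights, the value table and an estimated correlation (with 2, 6, 5 and 0 at an unadjusted p under 0.05), 2 with the mean of all probes, 6 with slide as a block, 6 with scan day as a block, 4 on scan day 1, 9 on slide 2, 3 on slide 3 and 6 without slide 2. Under quantile scaling 1 list was called, but the ribosomal call was lost (adjusted p = 0.0568) and oxidative phosphorylation gained one (0.0211). The cause was not tested. Leaving out 1 array gave 0 to 1 lists. The ribosomal list's adjusted p then ran from 0.00237 to 0.141 and lay above 0.05 without HFP 2 (0.0610), 3 (0.0573), 4 (0.0675) or 6 (0.104) and without LFP 12 (0.0525), 15 (0.0604) or 18 (0.141). It was 0.558 with normexp and 0.000151 with the mean of all probes. Oxidative phosphorylation, not called and up, was called down with slide as a block (adjusted p = 0.00577), scan day as a block (0.0458) and on slide 2 (0.00991).

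The spread ratio of -0.10 was 0.48 with normexp and 0.0295 with quantile scaling, and -0.24 to 0.00504 (without LFP 18) with 1 array left out. The cause was not tested.

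All 24 largest differences kept their call under quantile and median scaling, the trended variance, array weights and the value table. The same held for the random slide block, which is no check against a slide effect. Calls were kept by 22 without a filter, 21 without slide 2 and 14 with normexp. With scan day as a fixed block 10 kept it, and with slide as a fixed block 7. Only 12 of the 24 remained under the filter on all 18 arrays, and these 12 kept their call. In the fits where a gene had a value, leaving out 1 array ended the call of 2 of the 24 and of 24 of the 57 other named genes called, and reversed 0. Without LFP 11, 12, 13, 14, 15, 17 or 18, only 23 of the 24 passed the filter on dim probes. A gene removed by that filter is not counted as a lost call. Calls lost in more than 9 of the 18 such fits were those of PSMD7 (17), BHLHE40 (14), COL3A1 (14), ESAM (14), FAM3D (13), NR4A3 (13), TAPBP (13), CABCOCO1 (12), NDUFA6 (12), AQP4 (11), OLIG2 (11), HBB (10) and LUM (10). Of the 66 named genes not called, 31 gained a call without at least 1 array, GRM3, HTR2C and EGR4 among them. Of the 147 named genes, 4 called ones changed sign with normexp: SULT2B1 0.0743, ESAM 0.0960, HTR1E 0.0145 and HBB 0.0883. With slide as a block they included VPS37B 0.0879, AQP4 -0.00440 and ESAM 0.00917. With scan day as a block, and on scan day 1 alone, they included VPS37B 0.0838, AQP4 -0.0194 and ESAM 0.0109. On slide 2 they included VPS37B 0.0435, AQP4 -0.0295, PSMD7 -0.0260, OLIG2 -0.0341, NFIL3 0.0730, ENPP6 -0.0345 and FKBP5 -0.19, and on slide 3 VPS37B 0.13, ESAM 0.0691 and BHLHE40 0.00342. The cause was not tested.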

Other observations

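The groups and probes in the first 2 paragraphs were chosen after their values were seen, and no test here was written after its result was seen. Of 39 probes for the mitochondrial genome, 12 passed in limma, or 30.8% against 12.4% of all probes, and these 12 were all higher in HFP by 0.20 to 0.58. The other 27 did not pass, and this group was not tested as a set. The 12 belong to some genes of complex I, complex IV and ATP synthase. ND4L rose by 0.58, ND3 by 0.52 (0.40 on its brighter probe), ATP8 by 0.28 and COX3 by 0.29 on 1 probe. ND1, ND2, ND5, COX2 and ATP6 also had probes that rose. The brightest probes of COX3 (0.06, adjusted p = 0.737), COX2 (0.12, 0.482), ND5 (0.000654, 0.996) and ND1 (0.18, 0.122) did not pass in limma. COX1, CYTB, ND4 and ND6 had no probe that passed. All 12 kept their sign under normexp, quantile and median scaling, in the value table and with scan day or slide as a block, but 2 passed with the former block and 0 with the latter. Calls were left for 9 of the 12 with normexp, 9 with quantile scaling and 8 in the value table. Chromosome 16, the chromosome of the MHC, had, together with its unplaced sequence, 40 of 155 probes called, or 25.8% against 12.4% of all probes, 36 lower and 4 higher in HFP. All 40 kept their sign with scan day as a block, where 7 passed, and 1 passed with slide as a block. With normexp 37 kept their sign and 23 passed, and their median went from -1.06 to -0.59. On unplaced W chromosome sequence 8 of 48 probes passed, or 16.7% against the same 12.4%, all higher in HFP under each scaling. Of these 8, 7 kept their sign and 1 passed with scan day as a block, none passed with slide as a block, and 6 and 5 kept their sign within slides 2 and 3. Their median of 0.32 became 0.10 with scan day as a block.

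Single probes gave the largest differences of all. An unnamed clone probe differed by -10.83, was not well above background on any HFP array and was on all 9 LFP arrays, with an SD of 3.25 within LFP. The bound was at least 373-fold lower, and the difference with scan day as a block was -11.52 (adjusted p = 0.00287). Both log2 differences of this probe rest on HFP signals near background, so only the bound holds. AvBD4, an antimicrobial beta-defensin, was higher by 1.08 (adjusted p = 0.0236) on its brighter probe and by 4.07 on another, well above background on 2 LFP arrays. That 4.07 became 2.26 with scan day as a block (adjusted p = 0.309) and 0.85 within slide 2. MRPS28, of the mitochondrial ribosome, differed by -4.35 on one probe, but by -1.19 with scan day as a block (adjusted p = 0.910) and by 2.82 within slide 3, and stood at 0.02 on the other probe. BLB2, an MHC class II beta chain, had a probe as low as -2.62 and another as high as 1.08, both past the threshold.

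The number of probes that differ between the lines exceeded chance: 1 of 100 splits of the 18 arrays into 9 and 9, the real one, gave as many, with 4567 in the real split and 570 in the highest of the others. For slide or scan day as the whole cause, probes called between HFP of slide 1 and LFP of slides 4 and 5 were followed into slides 2 and 3, where 82.7% of the 1194 with a value kept their sign, against 76.7% in the highest of the 15 other choices of 1 array per slide and 23.7% to 49.0% where both chosen arrays were HFP. The choices of HFP arrays only set the LFP array among the others, so their low share is partly built in and is no measure of chance. The highest other choice, LFP 10 with HFP 8, held 1 LFP array. The 82.7% argues against scan day as the whole cause, though it rests on 1 LFP array per slide. The differences within those slides were 0.373 of the others at the median. Part of that fall may come from scan day and part from selecting the probes on the other slides, and VPS37B lay near 0 within slides 2 and 3. A sequence variant under the probe was tested through second probes: these had the sign of the first in 80.9% of 768 genes called (77.9% to 83.5%, Wilson) and 64.8% of 5774 not called, which argues against variants as the whole cause. A difference in brain expression between the lines stays open as a hypothesis, as do kinship and housing, which were not tested.

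The largest differences may be a separate case. Of 78 probes that differed by 4-fold or more (29 higher, 49 lower), 22 had a second probe of the gene, and it had the same sign in 77.3% (17 of 22, exact interval 54.6% to 92.2%), with a median ratio of 0.128. For these a sequence variant under the probe and a change in transcript level cannot be told apart, because second probes are few and a diverged haplotype, as in the MHC, could lower several probes at once.

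Genes that differed lay next to each other on chromosomes more often than shuffled calls: with 1 probe per 50 kb there were 162 neighbouring pairs among 1009 of 8585 loci, against 99 to 137 in 95% of 1000 shuffles and 151 at most. Several probes of 1 transcript are not excluded by this, because probes under different names on either side of a 50 kb boundary both counted. Of the pairs 58.6% had 1 sign, against 51.6% of all neighbours. Neighbouring genes that vary together whatever the line could not be excluded: 4 of 100 splits gave as many pairs, the highest other 176 against the real 162, too few draws to place the share under 5 in 100. Of 807 windows of 1 Mb, 0 passed a hypergeometric test of their calls and 33 had an unadjusted p under 0.05.

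For the gene lists chance is not excluded. With the preset correlation 94 of 100 splits called at least the 1 list of the real split, and the highest other split called 14.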
